A study of Mus musculus with 8 samples.

How the data were processed

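RNA was measured in intestinal epithelial cells of the mouse distal colon, released from the tissue by shaking in EDTA and DTT per the labels' protocols. Mice with floxed Rora alleles (WT) were compared with mice lacking Rora in the intestinal epithelium (KO). Each genotype was left untreated or given dextran sulfate sodium (DSS), a polymer that injures the colon lining. Per the labels, DSS was given at 2% (w/v) in drinking water for 5 days and was followed by 3 days of plain water. The 8 libraries formed 4 groups of 2. Nothing in the labels says that the replicates of a group were separate animals, so every p-value measures only the spread between these samples, which may be technical.

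The deposited tables give an expected count per gene, in which RSEM shares reads that map to several places among genes, per the file headers. The deposited TPM values (transcripts-per-million) were corrected for effective gene length by the authors' RSEM step, per the file headers. The submitters' processing notes name STAR 2.5.3a, RSEM 1.3.0, DESeq2 1.18.1 and the genome build mm10, without stating which options were used. They state neither an annotation release nor a strand setting. Each table lists 53379 genes with versioned Ensembl identifiers joined to symbols. Between 9.17% and 9.75% of the listed genes had an expected count that was not a whole number. No test used the TPM or FPKM columns.

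Expected counts were rounded and analysed in R 4.3.3. Genes without enough counts in at least 2 libraries were removed with the default filterByExpr rule, which left 14991 genes. Libraries were scaled with TMM factors in edgeR 4.0.16. One quasi-likelihood model with a mean per group was fitted to all 8 libraries, with 4 residual degrees of freedom per gene. The comparisons were KO against WT within each treatment, DSS against untreated within each genotype, and the interaction, which is the DSS change in KO minus the DSS change in WT. Each p-value was two-sided and adjusted by the Benjamini-Hochberg method within its comparison, with a threshold of 0.05. Expression is given as counts-per-million (CPM) after TMM scaling, with the SD over 2 libraries. Fold changes are given on the log2 scale. The standard error (SE) beside them is the absolute fold change divided by the square root of the edgeR quasi-likelihood F statistic. For genes with few counts in a group it can fall below counting error. In the text, "higher" and "lower" members of a list are those past this threshold over all genes tested. Where a list is given with a single count, the count adjusted over the list alone was the same.

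Lists of genes for 29 pathways and cell types were tested with camera and fry in limma 3.58.1. The smooth muscle and the neuron and glia lists kept 2 genes each and were not tested, which left 27 lists per comparison. The preset correlation between genes in camera was 0.01, and each test was repeated with a correlation estimated from the data. Camera compares a list with all other genes, whereas fry asks only whether the members of a list changed. List p-values were adjusted over the lists within each comparison, and those given are from camera with its preset correlation unless fry or an estimated correlation is named. Chromosomal positions are those of GENCODE M21 for mm10, which held 99.8% of the deposited identifiers without their version and 94.8% with it.

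Where all libraries of a group had 0 counts, a fold is given only as a lower bound, computed against 3 counts over the group. Where a group held 1 to 3 counts, the ratio of CPM is given with its 95% exact counting interval. These intervals and bounds cover counting error only, since reads are not independent molecules. Per library, 3 counts corresponded to between 0.150 and 0.191 CPM.

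The groups, comparisons, tests, thresholds, the 29 lists, the rule for naming genes and all alternatives but one were fixed before the data were examined. The rule named Rora and Rorb. It named the 6 largest rises and the 6 largest falls of each comparison of 2 groups among genes past the threshold whose libraries did not overlap and whose mean was at least 5 CPM. Gene models without a proper symbol, pseudogenes, ribosomal protein genes, antigen receptor segments and haemoglobin genes were left out of that ranking. It also named up to 2 members per list with the smallest p-values, and Nfkbia, Tnf, Il1b, Il6 and Cxcl1 in the comparisons of genotypes. For the interaction it named the 4 largest positive and the 4 largest negative values among genes past the threshold with a mean of at least 5 CPM. The same kinds of gene were left out there, and overlap of libraries was not considered. Rankings of rises, falls or differences in the text refer to genes within these limits. Some genes that the rule names are not reported here. Other list members are given as examples and were chosen after their values were seen.

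The procedure was tested on simulated data with known changed genes in each comparison, drawn from the means, spreads and library sizes of the real samples. Changed genes were taken only from those with a mean of at least 5 CPM, and each gene had the same spread in all groups. The recovery that follows therefore does not cover genes with fewer counts. At a 1.5-fold change edgeR recovered 85.7% of changed genes for untreated KO against WT, among 14697 genes tested. The share was 95.3% for KO against WT under DSS, 96.9% for DSS in WT, 90.2% for DSS in KO and 73.6% for the interaction. At a 4-fold change it recovered 100% of changed genes in each of the 5 comparisons. The share of false calls ranged from 3.43% for DSS in WT to 8.84% for KO against WT under DSS. With no gene changed and the variance of the DSS-treated KO libraries inflated, between 0 and 6 genes were called per comparison. In that simulation 7.33% of genes in KO against WT under DSS and 7.86% for DSS in KO had an unadjusted p under 0.05. The share was 2.80% for untreated KO against WT, 2.46% for DSS in WT and 4.80% for the interaction. The shared spread thus made p-values too small in the first 2 comparisons and too large in untreated KO against WT and DSS in WT.

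The alternatives were DESeq2 size factors, library totals without composition scaling, the DESeq2 1.42.0 Wald test, limma-voom, no filter and a strict filter of 50 counts in 2 libraries, only the groups compared, the replicate number as a block, effective-length offsets, an added fold threshold of 1 on the log2 scale, and each of the 8 libraries left out in turn. Leaving out the mitochondrially encoded genes was added after the data were seen. No alternative split of the samples was tested, since groups of 2 allow too few splits.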

Results

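Expression was measured by RNA sequencing of distal colon epithelial cells in 8 libraries. There were 2 libraries for each of untreated WT, untreated KO, DSS-treated WT and DSS-treated KO mice. Totals of expected counts were 20418466 and 18163736 for untreated WT, 15971642 and 16566885 for untreated KO, 16529551 and 16879186 for DSS-treated WT, and 16975128 and 17062185 for DSS-treated KO. Between 20445 and 21045 genes had a count per library. The first principal component held 60.2% of the variance and ordered the groups from untreated through DSS-treated WT to DSS-treated KO. The second held 15.1% and set DSS-treated WT apart from the other groups. Mitochondrial genes took 8.05% and 7.75% of counts in untreated WT, 7.23% and 7.28% in untreated KO, and 7.45% and 7.50% in DSS-treated WT. In DSS-treated KO that share was 5.29% and 4.91%. Replicates differed by more than counting error alone, with a chi-square per degree of freedom of 2.23 in untreated WT, 1.29 in untreated KO, 1.86 in DSS-treated WT and 5.23 in DSS-treated KO. The common biological coefficient of variation was 3.49%.

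Rora, the deleted nuclear receptor gene (ENSMUSG00000032238.17, chromosome 9, 68653786 to 69388246), was near the detection limit in every library. The counts of the 2 libraries were 12 and 6 in untreated WT, 4 and 3 in untreated KO, 16 and 14 in DSS-treated WT, and 8 and 5 in DSS-treated KO. In CPM the means were 0.468 ± 0.187 (SD, n = 2) and 0.219 ± 0.0499 without DSS, and 0.893 ± 0.0970 and 0.373 ± 0.123 with DSS. The ratio of WT to KO was 2.18 (95% counting interval 0.869 to 6.18) without DSS and 2.39 (1.21 to 5.00) with DSS. By edgeR, KO against WT gave log2 fold-change = -1.10 ± 0.58 (SE, adjusted p = 0.238) untreated and -1.24 ± 0.45 (adjusted p = 0.0425) under DSS. The DSS call was lost without each of the 8 libraries in turn, with values from -1.61 to -0.94 and adjusted p up to 0.246. It was also lost with the DESeq2 Wald test (adjusted p = 0.286), and with effective-length offsets the value was -2.57. DSS itself gave Rora log2 fold-changes of 0.90 ± 0.42 in WT (adjusted p = 0.111) and 0.75 ± 0.62 in KO (adjusted p = 0.359). Gene-level counts do not show whether the floxed exon was present. Its paralog Rorb had too few counts for the test, with 18 in untreated WT against 4 in untreated KO (ratio 3.82, 1.26 to 15.5) and 15 against 3 under DSS (ratio 5.18, 1.47 to 27.9).

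The comparison of untreated KO with untreated WT asked what loss of Rora changed in the uninjured colon epithelium. Genes of antigen presentation, interferon-induced GTPases, cholesterol synthesis and cell division were higher in KO. Cd74, the invariant chain of class II molecules (ENSMUSG00000024610.14, chromosome 18, 60803848 to 60812652), rose from 27.9 ± 0.429 to 83.8 ± 0.124 CPM (SD, n = 2 per group), with log2 fold-change = 1.59 ± 0.07 (SE, adjusted p = 3.92e-09). Iigp1, an interferon-inducible GTPase (ENSMUSG00000054072.11, chromosome 18, 60376027 to 60392634), rose from 5.43 ± 0.465 to 24.8 ± 1.95 CPM (2.19 ± 0.11, adjusted p = 2.77e-08). Slc37a2, a sugar-phosphate transporter (ENSMUSG00000032122.15, chromosome 9, 37227585 to 37255738), fell from 366 ± 1.32 to 183 ± 1.52 CPM (adjusted p = 3.92e-09). In total 1378 genes were higher and 932 lower among 14991 tested, and 106 and 38 of these differed by at least 2-fold. The number at an unadjusted p under 0.05 was 4216.

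Other large rises in untreated KO were in Tgtp1 (log2 fold-change = 2.35 ± 0.13), another interferon-inducible GTPase with a close paralog, Ido1 (1.99 ± 0.24), which degrades tryptophan, and Alpi (1.59 ± 0.10), an intestinal alkaline phosphatase. Reg3b, an antimicrobial lectin (ENSMUSG00000071356.7, chromosome 6, 78370657 to 78373466), had 8 counts in untreated WT and 45 in untreated KO (2.69 ± 0.52, adjusted p = 0.00274). Without untreated KO replicate 2 its value was 2.22 and the call was lost (adjusted p = 0.057), and without untreated WT replicate 1 it was 4.47. Besides Slc37a2, the largest falls were in the manganese transporter Slc30a10 (-1.51 ± 0.12), the sialyltransferase St8sia5 (-1.01 ± 0.14), the stress cytokine Gdf15 (-0.93 ± 0.15), and the cytochrome P450 genes Cyp2d9 (-0.93 ± 0.09) and Cyp2d12 (-0.86 ± 0.06), which belong to a family of similar genes.

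In the antigen presentation list 13 of 16 measured genes were higher in untreated KO and 0 lower (15 higher adjusted over the list alone), led by Cd74 and the class II gene H2-Aa (log2 fold-change = 1.46 ± 0.09). The list had a median log2 fold-change of 0.97 and a camera adjusted p of 2.23e-32. Of 23 interferon-stimulated genes 10 were higher and 0 lower (median 0.29, adjusted p = 4.10e-11), led by the guanylate-binding protein gene Gbp2 (36.2 ± 0.480 to 101 ± 2.45 CPM, log2 fold-change = 1.48 ± 0.05). Cholesterol synthesis genes were higher for 19 of 20 measured (20 adjusted over the list alone, median 0.45, adjusted p = 2.90e-48), with Hmgcs1, an early enzyme of the pathway, at 0.69 ± 0.04 (271 to 436 CPM) and Cyp51 at 0.69 ± 0.04. Proliferation genes were higher for 22 of 23 (22 adjusted over the list alone, median 0.53, adjusted p = 7.40e-31), such as the topoisomerase gene Top2a (77.6 ± 1.93 to 120 ± 7.23 CPM, 0.63 ± 0.06) and the replication helicase gene Mcm5 (0.69 ± 0.06). Beside these rises, few single markers of immune cells were called. The macrophage list had 1 of 15 higher, the neutrophil list 2 of 12 lower, and the T and NK cell (9 measured) and B and plasma cell (10 measured) lists had 0 calls, with camera adjusted p = 0.638, 0.623, 0.552 and 0.263, though fry called the B and plasma cell list lower on balance (adjusted p = 0.016). The 2 lower neutrophil markers became 1 without untreated WT replicate 1 and 0 without any other untreated library. The neutrophil markers Ly6g and Cd177 stood at 98.2 and 165 CPM in untreated WT, where S100a8 had 0 counts.

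**Figure D1:**
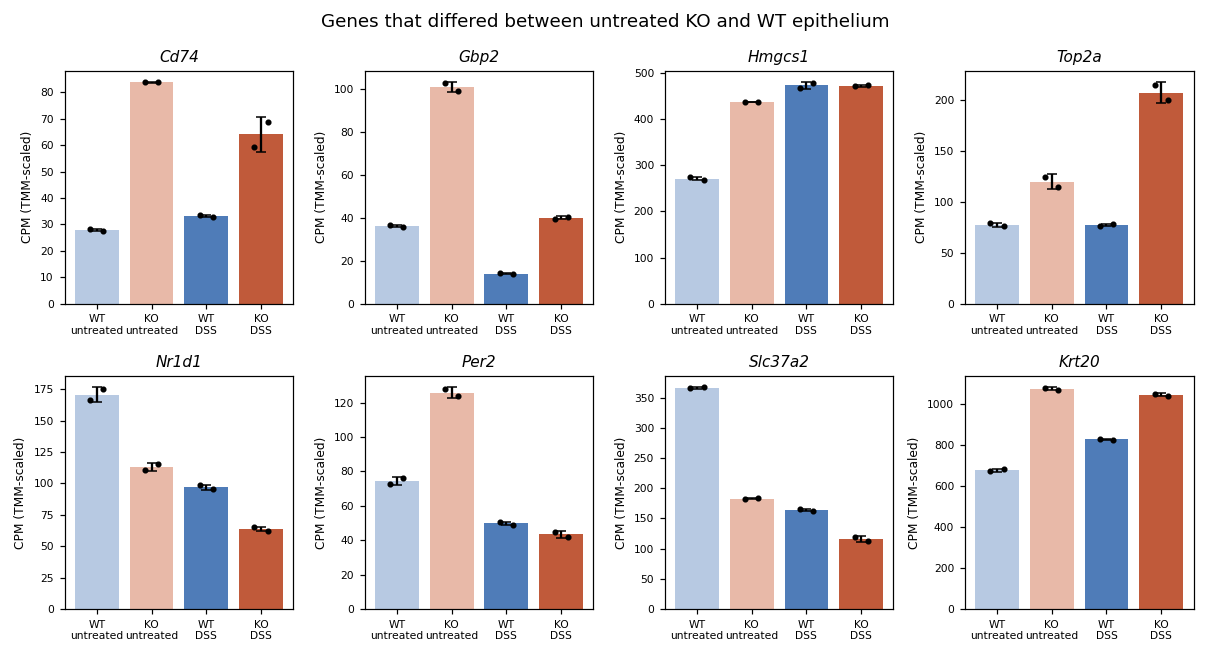
TMM-scaled CPM of 8 genes in the 4 groups, with bars for the mean, error bars for the SD and points for the 2 libraries of a group. Cd74 stood at 27.9 CPM in untreated WT and 83.8 CPM in untreated KO.

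Immediate-early genes of the dissociation stress list were lower in untreated KO for 8 of 13 and higher for 0 (9 lower and 1 higher adjusted over the list alone), such as Junb (log2 fold-change = -0.44 ± 0.05) and the phosphatase gene Dusp1 (-0.43 ± 0.05). The camera adjusted p was 9.80e-08, and 0.104 with an estimated correlation. Mitochondrially encoded genes were lower for 7 of 13 (9 adjusted over the list alone), mt-Nd6 among them (-0.37 ± 0.05), with adjusted p = 9.00e-05 and adjusted p = 0.359 with an estimated correlation. That count of 7 was 2 without untreated WT replicate 1, 4 without untreated WT replicate 2, 1 without untreated KO replicate 1, 4 without untreated KO replicate 2 and 11 without either DSS-treated KO library. The epithelial repair list had 6 of 15 higher, led by the progenitor-associated Ly6a (0.52 ± 0.05) and the annexin Anxa8 (0.39 ± 0.04). Its median was 0.10, its mean (which includes 2 genes at 3 counts or fewer) -0.14 and its camera direction up (adjusted p = 0.00331, and adjusted p = 0.119 with an estimated correlation).

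Camera made no call for any list of this paragraph, while fry called the unfolded protein response (adjusted p = 0.016) and tight junction (0.0316) lists on balance. Clock genes went both ways (4 higher and 2 lower of 15, adjusted p = 0.436), where the repressor Per2 rose by 0.76 ± 0.05 and Nr1d1, a receptor that competes with ROR proteins for DNA sites, fell (log2 fold-change = -0.60 ± 0.05). Fatty acid oxidation genes were 2 higher and 6 lower of 19 (adjusted p = 0.57), with the lipid carrier Fabp2 at 0.87 ± 0.05 and the lipid droplet coat Plin2 at -0.40 ± 0.05. Among NF-κB target genes 3 of 30 were higher and 3 lower (5 and 3 adjusted over the list alone, median -0.02, mean 0.05, camera direction down, adjusted p = 0.894), where 6 members had 3 counts or fewer in a group, so that the median and mean rest partly on them. The inhibitor Nfkbia fell from 57.4 to 45.3 CPM (-0.34 ± 0.05, adjusted p = 0.00046). Tnf (-0.41, adjusted p = 0.633) and Il1b (-0.34, adjusted p = 0.809) passed no threshold, Cxcl1 had 3 counts in each genotype, and Il6 had too few counts for the test. Antimicrobial genes were 5 higher and 4 lower of 19 (6 and 4 adjusted over the list alone, adjusted p = 0.436), with the protease inhibitor Slpi at 1.21 ± 0.13 and the acute-phase Saa1 at -0.57 ± 0.06. Unfolded protein response genes were 6 higher and 2 lower of 15 (7 and 2 adjusted over the list alone, adjusted p = 0.105), including the chaperones Hspa5 (0.42 ± 0.04) and Hsp90b1 (0.24 ± 0.04). Tight junction genes were 4 higher of 17 (5 higher and 1 lower adjusted over the list alone, adjusted p = 0.105), Cldn4 among them (0.67 ± 0.07). These counts moved when 1 library was left out. The 6 lower fatty acid oxidation genes became 2 without either untreated WT library, 1 without either untreated KO library and 3 without either DSS-treated WT library. The 4 higher tight junction genes became 2 without untreated WT replicate 2 and 1 without the other untreated libraries or either DSS-treated WT library. The 6 higher unfolded protein response genes became 2 without untreated KO replicate 1. The 5 higher antimicrobial genes became 3 without untreated WT replicate 2 or untreated KO replicate 1 and 2 without untreated KO replicate 2. The 3 higher NF-κB targets became 5 without either DSS-treated KO library.

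Markers of epithelial cell types also went both ways. Colonocyte genes were 6 higher and 5 lower of 20 (6 and 6 adjusted over the list alone, adjusted p = 0.946), with the surface keratin Krt20 rising from 676 to 1073 CPM (log2 fold-change = 0.67 ± 0.04) and the phosphate carrier Slc20a1 falling (-0.58 ± 0.04). Goblet cell genes were 3 higher and 4 lower of 12 (5 and 5 adjusted over the list alone, adjusted p = 0.991), with Retnlb at 0.45 ± 0.05 and the mucus protein gene Clca1 at -0.23 ± 0.03. Stem and crypt genes were 2 higher and 4 lower of 14 (2 and 6 adjusted over the list alone, adjusted p = 0.436), with Prom1 at 0.36 ± 0.04 and Cd44 at 0.59 ± 0.09. Enteroendocrine genes were 2 higher and 2 lower of 10 (3 and 2 adjusted over the list alone, adjusted p = 0.894), with the serotonin enzyme Tph1 at 0.49 ± 0.09. General epithelial genes were 4 higher of 10 (adjusted p = 0.0652), such as Krt8 (0.27 ± 0.04) and the gut identity factor Cdx2 (0.34 ± 0.05). The tuft cell (7 measured, adjusted p = 0.677), sex-linked (4, adjusted p = 0.895) and erythrocyte (5, adjusted p = 0.895) lists had 0 calls. Fibroblast markers were 2 higher of 8 (3 adjusted over the list alone, adjusted p = 0.436) and endothelial markers 2 lower of 4 (adjusted p = 0.25), and both counts became 0 or 1 without any untreated library. Smooth muscle markers had 0 calls of 2 (1 higher adjusted over the list alone) and neuron and glia markers 0 of 2. The 5 lower colonocyte genes became 3 without either untreated KO library, the 4 lower stem genes became 2 without untreated WT replicate 1 and 1 without untreated KO replicate 1, and the 3 higher goblet genes became 5 without either DSS-treated KO library.

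Across the 27 lists in untreated KO against WT, camera called 7 with its preset correlation and 4 with an estimated one, and fry called 11 on balance and 22 in either direction. Besides the lists named above, the general epithelial list was called by fry (adjusted p = 0.0327) and not by camera. The cholesterol (adjusted p = 0.00228), proliferation (0.00273), antigen presentation and interferon (0.0213 each) calls held with an estimated correlation. The count of 2310 genes was 1094 without untreated WT replicate 1, 1226 without untreated WT replicate 2, 953 without untreated KO replicate 1 and 991 without untreated KO replicate 2. The DESeq2 Wald test gave 1246 and effective-length offsets 1290.

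The comparison of DSS-treated KO with DSS-treated WT asked how the injured epithelium differed with and without Rora. Inflammatory, neutrophil and cell division genes were higher in KO, and genes of fat oxidation, mature colonocytes and goblet cells were lower. Lrg1, a secreted glycoprotein of inflamed tissue (ENSMUSG00000037095.7, chromosome 17, 56119678 to 56122001), rose from 3.90 ± 0.182 to 130 ± 8.23 CPM (SD, n = 2 per group), with log2 fold-change = 5.05 ± 0.10 (SE, adjusted p = 1.83e-13). The nitric oxide synthase gene Nos2 (ENSMUSG00000020826.8, chromosome 11, 78920787 to 78960254) rose from 15.1 ± 0.681 to 93.4 ± 0.800 CPM (2.63 ± 0.06, adjusted p = 1.53e-12). Fabp2, an intestinal fatty acid carrier (ENSMUSG00000023057.5, chromosome 3, 122895072 to 122899506), fell from 112 ± 3.22 to 34.4 ± 1.65 CPM (-1.71 ± 0.06, adjusted p = 4.70e-11). Of 14991 genes 3198 were higher and 2657 lower, and 628 and 300 of these differed by at least 2-fold. An unadjusted p under 0.05 was found for 7114.

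The largest rises after Lrg1 were in the neutrophil products Retnlg (log2 fold-change = 5.04 ± 0.25), S100a8 (4.91 ± 0.12, 1.84 to 55.6 CPM) and S100a9 (4.65 ± 0.10, 3.60 to 90.2 CPM), the acute-phase gene Saa3 (4.47 ± 0.15, 1.10 to 24.6 CPM) and the chemokine gene Cxcl5 (3.97 ± 0.24). The largest falls were in Arhgap20 (-2.46 ± 0.12), the kinase gene Prkg2 (-2.28 ± 0.20), the cytochrome P450 gene Cyp2c55 (-2.27 ± 0.05, 235 to 48.9 CPM), the class I-like gene H2-T3 (-2.20 ± 0.15), the mucin glycosylation gene B3gnt6 (-2.15 ± 0.13) and Fndc5 (-2.03 ± 0.26). Both rankings are among genes with a mean of at least 5 CPM.

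Among NF-κB targets 21 of 30 were higher and 2 lower in DSS-treated KO (21 and 3 adjusted over the list alone), with a median of 1.12 and a camera adjusted p of 2.99e-29. The cytokine gene Il1b rose from 9.07 to 70.9 CPM (log2 fold-change = 2.97 ± 0.08), Tnf from 1.99 to 7.14 CPM (1.84 ± 0.22), and Nfkbia from 49.1 to 78.2 CPM (0.67 ± 0.05, adjusted p = 1.14e-07). Cxcl1 had 3 counts in DSS-treated WT and 46 in DSS-treated KO, a ratio of 14.8 (4.76 to 74.4). The 2 lower members were Relb (-0.16) and Traf1 (-0.42), chosen after their values were seen, and they became 1 without DSS-treated WT replicate 1 or DSS-treated KO replicate 1 and 0 without DSS-treated WT replicate 2. Of 19 antimicrobial genes 10 were higher and 5 lower (10 and 7 adjusted over the list alone, adjusted p = 1.36e-06). In the same libraries 11 of 12 neutrophil markers were higher and 0 lower (adjusted p = 1.33e-40). Macrophage markers were higher for 8 of 15 (adjusted p = 0.00118), with the endotoxin receptor Cd14 at 1.20 ± 0.05 and lysozyme Lyz2 at 1.05 ± 0.14, and this count was 5 without DSS-treated WT replicate 2. T and NK cell markers had 0 of 9 calls (adjusted p = 0.85), and B and plasma cell markers had 0 higher and 2 lower of 10 (0 lower adjusted over the list alone, 0 or 1 lower without any 1 library, adjusted p = 0.166). Fibroblast markers were 6 higher and 1 lower of 8 (adjusted p = 0.0852), with the matrix gene Fn1 at 0.87.

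Interferon-stimulated genes were higher for 16 of 23 in DSS-treated KO (adjusted p = 1.81e-08), with Gbp2 at 1.51 ± 0.07 and the nucleic acid sensor Zbp1 at 1.03 ± 0.06. Antigen presentation genes were higher for 15 of 16 (adjusted p = 3.64e-13), such as the peptide transporter Tap1 (1.02 ± 0.06) and the immunoproteasome subunit Psmb8 (1.16 ± 0.07). All 23 proliferation genes were higher (median 1.28, adjusted p = 2.13e-64), with Top2a rising from 77.6 to 208 CPM (1.42 ± 0.05) and the cyclin gene Ccna2 by 1.41 ± 0.06. Epithelial repair genes were higher for 11 of 15 (13 adjusted over the list alone, adjusted p = 2.09e-09), with Ly6a rising from 210 to 646 CPM (1.63 ± 0.04) and the urokinase receptor Plaur by 1.41 ± 0.11. Unfolded protein response genes were 11 higher and 1 lower of 15, with Hspa5 at 0.52 and Hsp90b1 at 0.50 (adjusted p = 0.00205, and adjusted p = 0.177 with an estimated correlation).

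Fatty acid oxidation genes were 1 higher and 12 lower of 19 in DSS-treated KO (adjusted p = 1.84e-09), Fabp2 among the lower. Colonocyte genes were 3 higher and 12 lower of 20 (3 and 13 adjusted over the list alone, adjusted p = 2.81e-07), Cyp2c55 and Slc20a1 (-0.62) among the lower. Goblet cell genes were 0 higher and 5 lower of 12 (6 lower adjusted over the list alone, adjusted p = 0.0007), with Clca1 falling from 1313 to 770 CPM (log2 fold-change = -0.77 ± 0.03) and the mucin Muc2 from 3092 to 1911 CPM (-0.69 ± 0.05). Without DSS-treated KO replicate 1, 3 goblet genes were higher. All 13 mitochondrially encoded genes were lower, such as mt-Co1 (-0.67 ± 0.04) and mt-Nd4 (-0.53), with adjusted p = 2.89e-10 and adjusted p = 0.0586 with an estimated correlation. Enteroendocrine genes were lower for 6 of 10, including the proglucagon gene Gcg (-0.86) and the granin Chgb (-0.43), with adjusted p = 0.00526 and adjusted p = 0.0819 with an estimated correlation, and this count was 3 without DSS-treated WT replicate 1. Clock genes were 4 higher and 7 lower of 15, with Nr1d1 at -0.60 and Per3 at -0.53 (adjusted p = 0.0156, and adjusted p = 0.272 with an estimated correlation). Erythrocyte markers were lower for 4 of 5 (adjusted p = 9.02e-05), Hba-a1 (-1.03), which has a near-identical copy, among them.

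**Figure D2:**
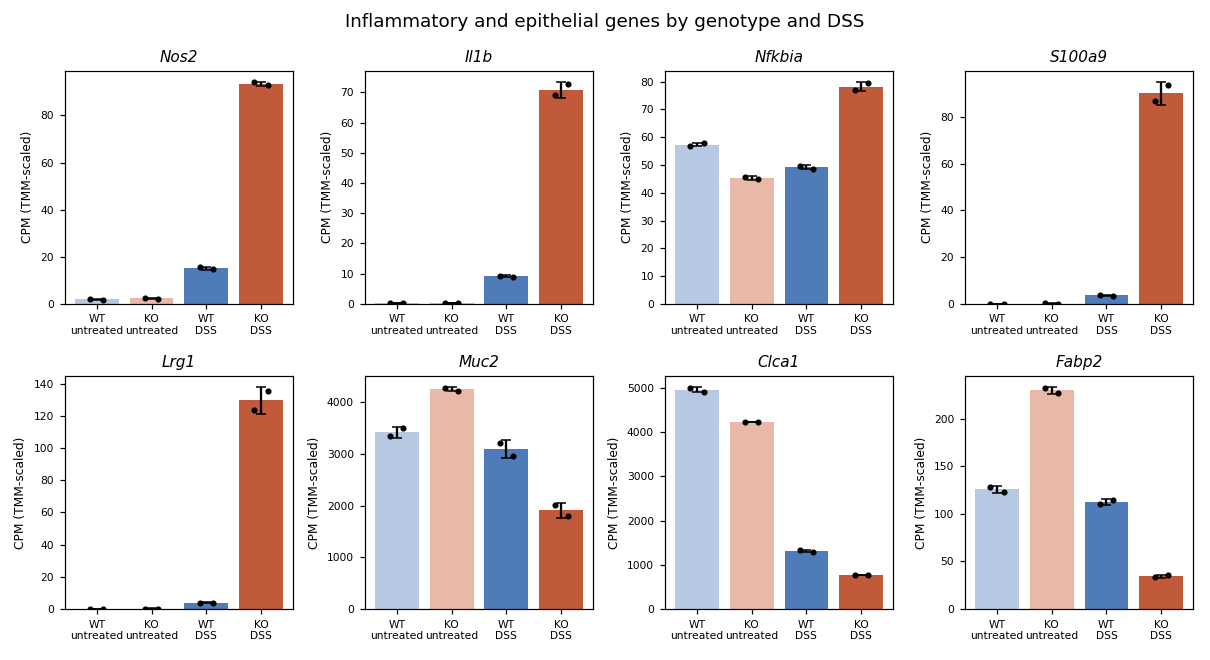
TMM-scaled CPM of 8 genes in the 4 groups, with bars for the mean, error bars for the SD and points for the 2 libraries of a group. Nos2 stood at 15.1 CPM in DSS-treated WT and 93.4 CPM in DSS-treated KO.

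Lists without a camera call in DSS-treated KO against WT were cholesterol synthesis (7 higher and 3 lower of 20, adjusted p = 0.166), with Fdps at 0.36, where the 3 lower were 1 without DSS-treated WT replicate 2. Tight junction genes were 4 higher and 3 lower of 17 (adjusted p = 0.986), with Cldn8 at 0.81 and Cldn15 at -0.48. Dissociation stress genes were 5 higher and 2 lower of 13 (adjusted p = 0.252), with Ier3 at 1.38 and Jun at -0.69. General epithelial genes were 3 higher and 2 lower of 10 (adjusted p = 0.982), with Elf3 at 0.27 and Cdx2 at -0.45. Stem and crypt genes were 2 higher and 6 lower of 14 (3 and 6 adjusted over the list alone, adjusted p = 0.166), with Cd44 at 0.53 and Prom1 at -0.27. Tuft cell genes were 2 higher and 1 lower of 7 (median 0.80, mean -0.01 including 1 gene at 2 counts, adjusted p = 0.769). The sex-linked list had 2 of 4 lower (adjusted p = 0.308), the endothelial list 1 higher and 1 lower of 4 (1 and 2 adjusted over the list alone, adjusted p = 0.878), the smooth muscle list 1 lower of 2 and the neuron and glia list 0 of 2. Of 27 lists camera called 16 with its preset correlation and 12 with an estimated one, and fry called 22 on balance and 27 in either direction. Fry alone called cholesterol synthesis (adjusted p = 0.000735), dissociation stress (0.0122) and fibroblast genes (0.00134) higher, and sex-linked, stem and crypt (0.00585 each) and B and plasma cell genes (0.00106) lower. With an estimated correlation the calls that held were proliferation (adjusted p = 0.00122), NF-κB and neutrophil (0.00182 each), fatty acid oxidation and repair (0.0157 each), colonocyte (0.0195), interferon (0.0212), antigen presentation, antimicrobial and erythrocyte (0.0436 each), goblet (0.0469) and macrophage (0.0477). The DESeq2 Wald test called 3801 genes in place of 5855.

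In the comparison of DSS-treated with untreated WT, the response of the normal epithelium to injury was measured. Among the genes named by the rule with more than 3 counts in untreated WT, Reg3b rose most. Most genes of the colonocyte and dissociation stress lists fell. Reg3b rose from 0.203 ± 0.208 to 180 ± 3.12 CPM (SD, n = 2 per group), with log2 fold-change = 9.69 ± 0.16 (SE, adjusted p = 2.19e-14). It had 8 counts in untreated WT, and without untreated WT replicate 1 or 2 the value was 11.47 or 8.98. Ang4, a secreted ribonuclease active against bacteria (ENSMUSG00000060615.5, chromosome 14, 51763878 to 51773590), fell from 186 ± 9.27 to 6.27 ± 0.12 CPM (-4.89 ± 0.07, adjusted p = 6.87e-15). The potassium pump gene Atp12a fell from 455 to 99.8 CPM (-2.19 ± 0.04). In total 2834 genes were higher and 2739 lower, and 522 and 279 of these differed by at least 2-fold. An unadjusted p under 0.05 was found for 6902.

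The other largest rises in WT were in Reg3g (log2 fold-change = 6.52 ± 0.13) and in genes with almost no counts before DSS, whose rank is uncertain. Acod1, an itaconate-producing enzyme gene of activated myeloid cells, was at least 24.7-fold higher, S100a8 at least 23.2-fold and Retnlg at least 9.37-fold. S100a9 had 1 count in untreated WT, a ratio of 136 (24.0 to 5420). The largest falls after Ang4 were in Srp54a (-4.73 ± 0.32, and -2.32 with effective-length offsets), which has near-identical copies, the transcription factor Fosb (-2.87 ± 0.07), the calcium-binding S100g (-2.72 ± 0.23), the ion transport regulator Fxyd4 (-2.48 ± 0.08) and St8sia5 (-2.43 ± 0.17).

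Antimicrobial genes were 11 higher and 6 lower of 19 in DSS-treated WT (adjusted p = 0.000256, and adjusted p = 0.0657 with an estimated correlation). NF-κB targets were 15 higher and 5 lower of 30 (16 and 5 adjusted over the list alone, adjusted p = 0.000207), with Nos2 at 3.03 ± 0.13 and Il1b at 5.21 ± 0.23, and the 5 lower were 3 without untreated WT replicate 1 and 2 without DSS-treated WT replicate 1. All 20 cholesterol synthesis genes were higher (adjusted p = 2.33e-27), with Cyp51 at 1.00 ± 0.04 and Hmgcs1 at 0.80 ± 0.04. Neutrophil markers were 11 higher and 1 lower of 12 (adjusted p = 4.71e-07), and the lower one was Ly6g (98.2 to 43.5 CPM), while Cd177 rose from 165 to 419 CPM. Macrophage markers were higher for 12 of 15 (13 adjusted over the list alone, adjusted p = 0.000336), with Lyz2 at 1.66 ± 0.18 and Csf1r at 1.84 ± 0.26. B and plasma cell markers were higher for 8 of 10 (9 adjusted over the list alone), with Ighm at 1.91 ± 0.24, adjusted p = 0.00397 and adjusted p = 0.0657 with an estimated correlation. That count of 8 was 3 without untreated WT replicate 1, 5 without untreated WT replicate 2 and 4 without DSS-treated WT replicate 1. All 5 erythrocyte markers were higher (adjusted p = 5.34e-10), with Hba-a2 at 1.31 and Hba-a1 at 1.33.

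Colonocyte genes were 5 higher and 15 lower of 20 in DSS-treated WT (adjusted p = 5.64e-27), such as Atp12a and the chloride exchanger Slc26a3 (-1.14 ± 0.04). Goblet cell genes were 4 higher and 5 lower of 12 (4 and 6 adjusted over the list alone, adjusted p = 0.000323), with Clca1 falling from 4962 to 1313 CPM (log2 fold-change = -1.92 ± 0.04) and the mucus protein gene Fcgbp by 1.28. Dissociation stress genes were lower for 10 of 13 (adjusted p = 1.08e-44), the transcription factors Egr1 (-2.02 ± 0.05) and Fosb among them. Clock genes were 1 higher and 10 lower of 15 (1 and 11 adjusted over the list alone), with Dbp at -1.08 ± 0.06 and Nr1d1 at -0.82 (adjusted p = 5.34e-09, and adjusted p = 0.0533 with an estimated correlation). Proliferation genes were 6 higher and 10 lower of 23, with the helicase genes Mcm6 at -0.91 ± 0.06 and Mcm3 at -1.08 ± 0.08 (adjusted p = 0.00572, and adjusted p = 0.0657 with an estimated correlation). Interferon-stimulated genes were 15 higher and 2 lower of 23, with Ifit2 at 1.95 ± 0.13 and Gbp2 at -1.36 ± 0.07 (adjusted p = 0.00268, and adjusted p = 0.0681 with an estimated correlation). Enteroendocrine genes were higher for 9 of 10, with Chgb at 1.27 ± 0.05 and Gcg at 0.91 ± 0.07 (adjusted p = 1.14e-06), and this count was 5 without DSS-treated WT replicate 1. Mitochondrially encoded genes were lower for 6 of 13 (7 adjusted over the list alone), with mt-Nd6 at -0.40 and mt-Nd5 at -0.32 (adjusted p = 0.0375, and adjusted p = 0.426 with an estimated correlation). This count was 3 without DSS-treated WT replicate 1 and 10 without either DSS-treated KO library.

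No camera call was made in WT for fatty acid oxidation (3 higher and 6 lower of 19, 3 and 7 adjusted over the list alone, adjusted p = 0.16), with Ucp2 at -0.50, or antigen presentation (5 higher of 16, adjusted p = 0.25), with B2m at 0.48 and H2-D1 at 0.28. The 5 higher were 3 without untreated WT replicate 2 or DSS-treated WT replicate 1. Unfolded protein response genes were 9 higher and 5 lower of 15 (10 and 5 adjusted over the list alone, adjusted p = 0.159), with Hsp90b1 at 0.50 and Hspa5 at 0.33, and the 9 were 5 without DSS-treated WT replicate 1. Repair genes were 4 higher and 5 lower of 15 (median -0.05, mean 0.29 including 2 genes at 3 counts or fewer, adjusted p = 0.505), with Ly6a at 0.74 and Sprr1a at 1.55, and the 5 were 3 without untreated WT replicate 1, either untreated KO library or either DSS-treated WT library. Tight junction genes were 5 higher and 2 lower of 17 (7 and 3 adjusted over the list alone, adjusted p = 0.274). General epithelial genes were 2 higher and 3 lower of 10 (3 and 4 adjusted over the list alone, adjusted p = 0.931), with Cdx2 at 0.40 and Lgals4 at -0.17. Stem and crypt genes were 4 higher and 7 lower of 14 (adjusted p = 0.945), with Prom1 at 0.88 and Cdca7 at -0.62. Tuft cell genes were lower for 3 of 7 (adjusted p = 0.0619), with the channel gene Trpm5 at -2.19 ± 0.24 and Dclk1 at -1.71 ± 0.32. The sex-linked list had 2 of 4 higher (3 adjusted over the list alone, adjusted p = 0.113), with the Y-linked Ddx3y at 0.39 and Kdm5d at 0.32. T and NK cell markers were 1 higher of 9 (0 adjusted over the list alone, adjusted p = 0.287), fibroblast markers 2 higher and 1 lower of 8 (adjusted p = 0.382) with Fn1 at 1.43 and Vim at 0.82, endothelial markers 1 lower of 4 (2 adjusted over the list alone, adjusted p = 0.408), and smooth muscle and neuron and glia markers 0 of 2 each.

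Of 27 lists in DSS-treated WT camera called 15 with its preset correlation and 9 with an estimated one, and fry called 25 on balance and 26 in either direction. Fry alone called antigen presentation (adjusted p = 0.0463), tight junction and repair (0.0222 each), unfolded protein response (0.0042), sex-linked (0.00108), T and NK cell (0.00513) and fibroblast genes (0.0214) higher, and fatty acid oxidation (0.00169), tuft cell (0.00281) and endothelial genes (0.0481) lower. The calls that held with an estimated correlation were cholesterol and colonocyte (adjusted p = 0.00376 each), dissociation stress (0.00592), erythrocyte (0.0181), neutrophil (0.0272), enteroendocrine (0.0318), and NF-κB, goblet and macrophage (0.0463 each). The count of 5573 genes was 3659 without DSS-treated WT replicate 1, and the DESeq2 Wald test gave 3409.

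The response to DSS in KO was measured in the same way. Several neutrophil and inflammatory genes rose from almost no counts, and Ang4 and most colonocyte and goblet cell genes fell. S100a8 was at least 595-fold higher, Retnlg at least 264-fold, Acod1 at least 241-fold and the prostaglandin synthase gene Ptgs2 at least 222-fold. S100a9 (ENSMUSG00000056071.12, chromosome 3, 90692632 to 90695721) had 3 counts before DSS, a ratio of 965 (330 to 4680), and stood at 90.2 ± 4.89 CPM (SD, n = 2) after it. Lrg1 rose from 0.220 ± 0.138 to 130 ± 8.23 CPM (log2 fold-change = 9.17 ± 0.16, SE, adjusted p = 1.27e-14). In total 3259 genes were higher and 2972 lower, and 738 and 587 of these differed by at least 2-fold. An unadjusted p under 0.05 was found for 7320.

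The largest falls in KO among genes with a mean of at least 5 CPM were in Ang4 (log2 fold-change = -5.51 ± 0.07), the protease gene Prss23 (-4.12 ± 0.15), the tubulin-associated Tppp3 (-3.68 ± 0.06, 125 to 9.73 CPM), Fndc5 (-3.39 ± 0.22), Odf3b (-2.97 ± 0.18) and Cyp2c55 (-2.96 ± 0.05). NF-κB targets were 23 higher and 2 lower of 30 (adjusted p = 2.10e-30), with Nos2 at 5.34 ± 0.09 and Il1b at 8.51 ± 0.15. Antimicrobial genes were 13 higher and 6 lower of 19 (adjusted p = 3.08e-10). All 12 neutrophil markers were higher (adjusted p = 9.39e-44), as were 14 of 15 macrophage markers (adjusted p = 1.90e-08), with Lyz2 at 3.45 ± 0.19 and Cd14 at 1.41 ± 0.05. T and NK cell markers were higher for 3 of 9 (adjusted p = 0.324), the granzyme Gzmb among them (2.21), and B and plasma cell markers for 4 of 10 (adjusted p = 0.122), with Ighm at 2.72 and Igkc at 2.58. The 3 were 1 without either untreated KO library and the 4 were 2 without DSS-treated KO replicate 2. Fibroblast markers were 5 higher and 1 lower of 8 (5 and 2 adjusted over the list alone, adjusted p = 0.134), with Fn1 at 2.70 and Vim at 1.15, and the 5 were 3 without untreated KO replicate 1.

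Proliferation genes were 15 higher and 2 lower of 23 in DSS-treated KO against untreated KO (adjusted p = 7.44e-10), with the cyclin genes Ccnb1 at 1.28 ± 0.06 and Ccna2 at 1.11 ± 0.06. Repair genes were 9 higher and 2 lower of 15 (adjusted p = 0.000143), with Ly6a at 1.85 ± 0.04 and Plaur at 1.81. Interferon-stimulated genes were 18 higher and 3 lower of 23 (adjusted p = 0.000148), with Ifit2 at 2.31 ± 0.12 and Gbp2 at -1.33. Unfolded protein response genes were 9 higher and 3 lower of 15, with Hsp90b1 at 0.76 and Hspa5 at 0.43 (adjusted p = 0.0055, and adjusted p = 0.226 with an estimated correlation), and the 3 were 1 without untreated KO replicate 2. Cholesterol synthesis genes were 12 higher and 3 lower of 20, with Msmo1 at 0.48 (adjusted p = 0.0104, and adjusted p = 0.0821 with an estimated correlation), and the 3 were 1 without either untreated KO library. Fatty acid oxidation genes were 1 higher and 10 lower of 19 (1 and 11 adjusted over the list alone, adjusted p = 1.34e-08), with Fabp2 at -2.74 ± 0.05.

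Colonocyte genes were 2 higher and 16 lower of 20 in KO given DSS (adjusted p = 5.70e-37), with Atp12a at -1.95 ± 0.04. Goblet cell genes were 3 higher and 8 lower of 12 (adjusted p = 1.53e-08), with Clca1 at -2.46 ± 0.04 and Fcgbp at -1.22. Clock genes were 2 higher and 11 lower of 15 (3 and 11 adjusted over the list alone, adjusted p = 8.58e-13), with Per2 at -1.54 ± 0.05 and Cry2 at -1.33 ± 0.06. Dissociation stress genes were 2 higher and 7 lower of 13 (adjusted p = 8.58e-13), with Egr1 at -1.94 and Fosb at -2.54. Mitochondrially encoded genes were lower for 12 of 13 (13 adjusted over the list alone), with mt-Co1 at -0.64 and mt-Nd5 at -0.77 (adjusted p = 5.15e-07, and adjusted p = 0.109 with an estimated correlation). Fry called antigen presentation (adjusted p = 0.0133), general epithelium (0.016), stem and crypt (0.0285), enteroendocrine (0.00352), tuft cell (0.00463), erythrocyte (0.0013), T and NK cell (0.00201), B and plasma cell (0.000175) and fibroblast genes (0.00125) on balance, but camera did not. The lists without a camera call were antigen presentation (9 higher and 5 lower of 16, adjusted p = 0.191), with H2-D1 and B2m at 0.69 each, tight junction (5 higher and 4 lower of 17, adjusted p = 0.974), with Tjp3 at 0.27 and Cldn8 at 0.29, and general epithelium (2 higher and 6 lower of 10, 2 and 7 adjusted over the list alone, adjusted p = 0.247), with Cdx2 at -0.39 and Krt8 at -0.28. Without untreated KO replicate 2 the 5 higher tight junction genes and the 6 lower epithelial genes were each 3. Stem and crypt genes were 4 higher and 7 lower of 14 (4 and 8 adjusted over the list alone, adjusted p = 0.507), with Slc12a2 at 0.52 and Axin2 at -0.66. Enteroendocrine genes were 5 higher and 2 lower of 10 (adjusted p = 0.234), with Chgb at 0.71 and Insl5 at 0.45, and tuft cell genes 2 higher and 3 lower of 7 (adjusted p = 0.196), with Trpm5 at -2.95 and Dclk1 at -3.67. Erythrocyte markers were 3 higher of 5 (adjusted p = 0.195), with Hbb-bs at 0.50 and the haem enzyme Alas2 at 1.70, the sex-linked list 1 higher of 4 (adjusted p = 0.796), endothelial markers 1 higher of 4 (adjusted p = 0.934), smooth muscle markers 1 lower of 2, with Mylk at -0.50, and neuron and glia markers 0 of 2.

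Of 27 lists in KO given DSS camera called 15 with its preset correlation and 12 with an estimated one, and fry called 24 on balance and 26 in either direction. The calls that held with an estimated correlation were NF-κB, colonocyte and neutrophil (adjusted p = 0.00174 each), fatty acid oxidation, goblet, macrophage and proliferation (0.0136 each), antimicrobial (0.0156), dissociation stress (0.0214), clock (0.03), repair (0.033) and interferon (0.0427). DESeq2 called 4314 genes in place of 6231.

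**Figure D3:**
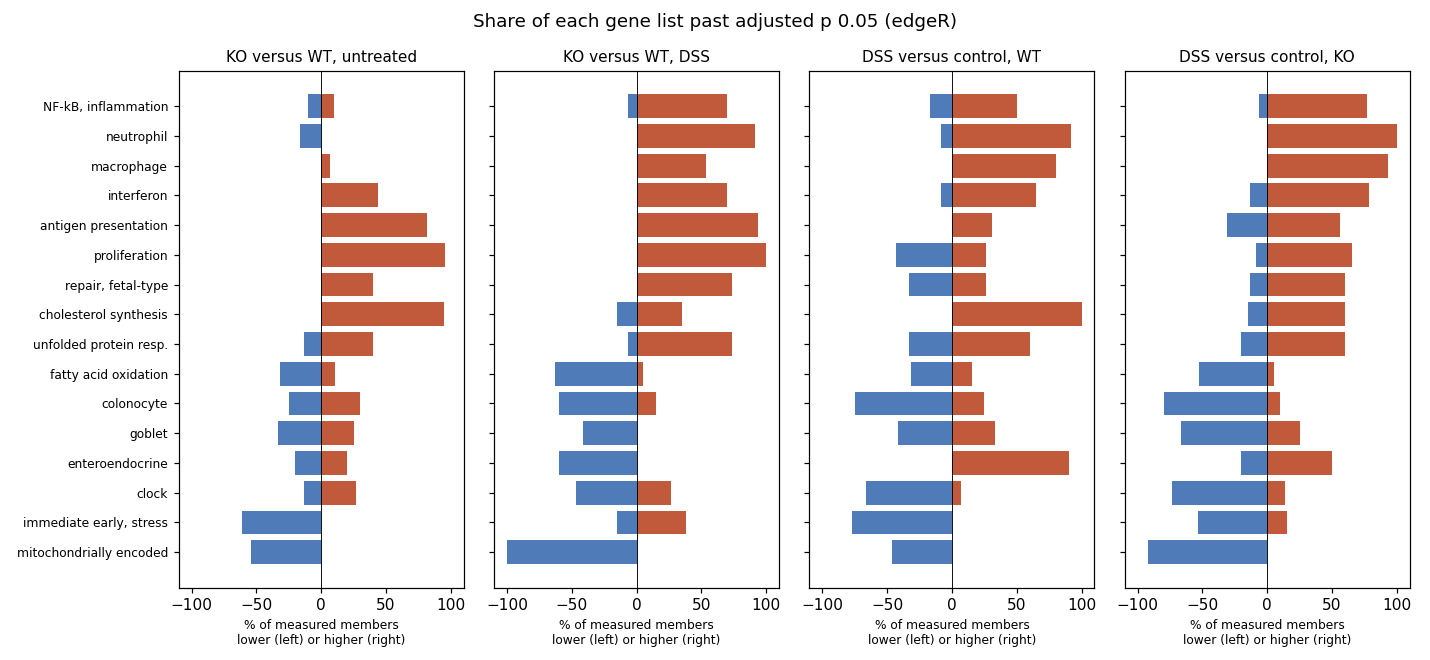
Percent of the measured members of 16 gene lists that were lower (left of 0) or higher (right of 0) at adjusted p under 0.05 in the 4 comparisons of 2 groups. For NF-κB targets in DSS-treated KO against DSS-treated WT, 21 of 30 members were higher and 2 lower.

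The interaction compared the DSS response of KO with that of WT. Inflammatory and cell division genes had a more positive response in KO, and genes of cholesterol synthesis, fat oxidation and colonocytes a more negative one. Among genes past the threshold with a mean of at least 5 CPM, Saa3 had the largest positive difference (log2 difference = 5.31 ± 0.54, SE, adjusted p = 1.06e-05), followed by Lrg1 (4.61 ± 0.99, adjusted p = 0.00477), the granule proteoglycan Srgn (3.82 ± 0.60) and Srp54a (3.42 ± 0.45, and 1.45 with effective-length offsets). Lrg1 had 6 and 7 counts in untreated WT and KO, and without untreated WT replicate 1 its value was 3.22 (adjusted p = 0.325). Srgn had 16 counts in untreated WT and 6 in untreated KO. Within the same limits the largest negative differences were in H2-T3 (-3.40 ± 0.19), Reg3b (-3.28 ± 0.51, and -5.07 without untreated WT replicate 1), Prkg2 (-3.17 ± 0.25) and the lipid transporter Abca12 (-2.97 ± 0.23). In total 1613 genes had a positive and 1595 a negative difference, of which 233 and 315 were at least 2-fold, and 5114 had an unadjusted p under 0.05.

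Proliferation genes had a positive interaction for 22 of 23 (23 adjusted over the list alone, median 0.78, adjusted p = 2.74e-27), and NF-κB targets for 16 of 30 with 1 negative (17 and 2 adjusted over the list alone, adjusted p = 4.17e-06), including 6 members with 3 counts or fewer in an untreated group. Cholesterol synthesis genes had a negative interaction for 17 of 20 (18 adjusted over the list alone, adjusted p = 2.30e-14). Under DSS they were still 12 higher and 3 lower in KO, against 20 higher in WT. In untreated KO 19 of 20 were already higher than in untreated WT. Fatty acid oxidation genes were 2 positive and 6 negative of 19 (2 and 8 adjusted over the list alone, adjusted p = 2.14e-09), and colonocyte genes 2 positive and 10 negative of 20 (3 and 11 adjusted over the list alone, adjusted p = 1.44e-08). These calls held with an estimated correlation, at adjusted p = 0.00677, 0.0267, 0.013, 0.0191 and 0.0191. The 2 positive colonocyte genes were 4 without DSS-treated KO replicate 1. Beside them, neutrophil markers gave 1 positive call of 12 (adjusted p = 0.0333, and adjusted p = 0.149 with an estimated correlation), with several members at 3 counts or fewer in untreated libraries. Macrophage markers gave 6 positive and 1 negative of 15 (adjusted p = 0.0019, and adjusted p = 0.0705 with an estimated correlation), and the 6 were 3 without untreated WT replicate 1 and 2 without untreated KO replicate 2.

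A further group of lists had an interaction call that was lost with an estimated correlation. Clock genes were 1 positive and 6 negative of 15 (1 and 8 adjusted over the list alone, adjusted p = 0.000767, and adjusted p = 0.19 with an estimated correlation). Repair genes were 7 positive and 1 negative of 15 (10 and 1 adjusted over the list alone, adjusted p = 0.000328, and adjusted p = 0.0512 with an estimated correlation), and dissociation stress genes 7 and 1 of 13 (8 and 2 adjusted over the list alone, adjusted p = 1.73e-05, and adjusted p = 0.0856 with an estimated correlation). Mitochondrially encoded genes were negative for 8 of 13 (10 adjusted over the list alone, adjusted p = 4.13e-05, and adjusted p = 0.179 with an estimated correlation), and 5 without untreated KO replicate 2 or DSS-treated WT replicate 1. Goblet cell genes were 1 positive and 5 negative of 12 (1 and 6 adjusted over the list alone, adjusted p = 0.000323, and adjusted p = 0.0512 with an estimated correlation), with 8 negative without DSS-treated KO replicate 2. Enteroendocrine genes were negative for 5 of 10 (adjusted p = 0.00261, and adjusted p = 0.0856 with an estimated correlation). Erythrocyte markers were negative for 3 of 5 (4 adjusted over the list alone, adjusted p = 7.81e-05, and adjusted p = 0.0512 with an estimated correlation). Unfolded protein response genes were 4 positive and 1 negative of 15 (5 and 1 adjusted over the list alone, adjusted p = 0.0429, and adjusted p = 0.337 with an estimated correlation), and the 4 were 2 without untreated WT replicate 1, untreated KO replicate 1 or DSS-treated WT replicate 1.

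Fry called the interaction on balance for the interferon (adjusted p = 0.00435), antimicrobial (0.0156) and sex-linked (0.0125) lists, but camera did not. The lists without a camera call were interferon (4 positive of 23, 5 and 1 negative adjusted over the list alone, adjusted p = 0.066), antigen presentation (6 positive and 4 negative of 16, median 0.11, mean -0.08, adjusted p = 0.515), antimicrobial (7 and 4 of 19, 8 and 5 adjusted over the list alone, adjusted p = 0.0701), and tight junction (2 and 7 of 17, 3 and 8 adjusted over the list alone, adjusted p = 0.318). Without untreated KO replicate 1 the 4 interferon genes were 2. The 4 negative antigen presentation genes were 2 without untreated WT replicate 1, untreated KO replicate 1 or DSS-treated WT replicate 1. The 7 negative tight junction genes were 2 without those libraries or untreated KO replicate 2, 4 without untreated WT replicate 2 and 3 without DSS-treated WT replicate 2. Stem and crypt genes were 1 positive and 4 negative of 14 (2 and 4 adjusted over the list alone, adjusted p = 0.398), and 2 negative without untreated WT replicate 1, either untreated KO library or either DSS-treated WT library. The general epithelial list had 1 positive and 3 negative of 10 (adjusted p = 0.22), tuft cells 2 and 1 of 7 (adjusted p = 0.886), the sex-linked list 2 negative of 4 (adjusted p = 0.268), fibroblasts 1 positive of 8 (adjusted p = 0.359) and smooth muscle 1 negative of 2. T and NK cell (9 measured, adjusted p = 0.743), B and plasma cell (10, adjusted p = 0.886), endothelial (4, adjusted p = 0.524) and neuron and glia (2) lists had 0 calls. Across 27 lists camera called 15 with its preset correlation and 5 with an estimated one, and fry called 18 on balance and 24 in either direction. The count of 3208 genes was 1914 without untreated WT replicate 1, 1891 without untreated KO replicate 1, 1985 without untreated KO replicate 2 and 1903 without DSS-treated WT replicate 1, and DESeq2 gave 1684.

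**Figure D4:**
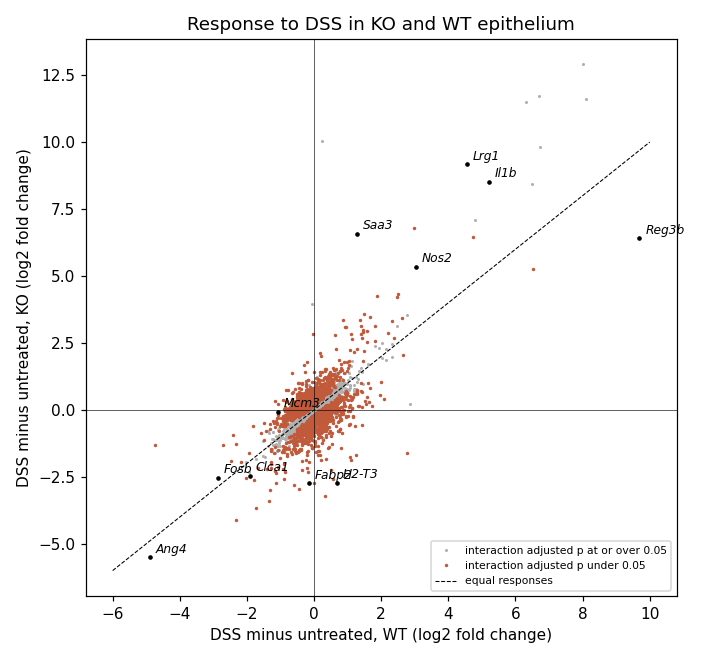
Log2 fold-change under DSS in WT (x axis) against that in KO (y axis) for 10561 genes, with the 2808 whose interaction had an adjusted p under 0.05 in red and a dashed line of equal change. Nos2 rose by 3.03 in WT and by 5.34 in KO.

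Genes called in both comparisons of genotypes numbered 1498, with 783 higher in both (294 expected if the calls were independent), 429 lower in both (165 expected) and 286 in opposite directions. The DSS responses of WT and KO shared 3304 called genes, of which 1583 rose in both (616 expected), 1410 fell in both (543 expected) and 311 moved in opposite directions. All comparisons use the same estimate of spread for a gene, so the calls are not independent. Part of the overlap beyond the expected counts may come from that. Across genes, which are not independent replicates, the log2 fold-changes of the DSS responses had a Pearson correlation of 0.67, and those of the genotype comparisons 0.12. Among the 3208 genes with an interaction, 1290 were called for the response in KO alone, 815 in WT alone, 687 in both with the same direction, 311 in both with opposite directions and 105 in neither.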

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

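The tests on summed lymphocyte markers, mitochondrial share, genes without close paralogs, crypt markers and scaling were chosen only after the result was seen. For the tests on the pan-leukocyte list, the bounds were set before its values were computed. The list itself was not among the 29 fixed lists and was added after the data were seen. The values that follow are log2 differences between the DSS response of KO and that of WT, singled out because the edgeR interaction test found that the responses, or equally the genotype effects, differed. It called 3208 of 14991 genes at adjusted p under 0.05. The groups held 2 libraries each, too few to test single samples for being far from the others.

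The largest positive differences were Saa3 at 5.31, Lrg1 at 4.61 (3.22 without untreated WT replicate 1, where adjusted p = 0.325), Srgn at 3.82 and Srp54a at 3.42 (1.45 with effective-length offsets). The largest negative ones were H2-T3 at -3.40, Reg3b at -3.28 (-5.07 without untreated WT replicate 1), Prkg2 at -3.17 and Abca12 at -2.97. Both rankings cover genes past the threshold with a mean of at least 5 CPM. Srgn had 16 counts in untreated WT and 6 in untreated KO. Among inflammatory genes Il1b differed by 3.30, Nos2 by 2.31, Tnf by 2.24 and Nfkbia by 1.01. The macrophage marker Lyz2 differed by 1.80 and the matrix gene Fn1 by 1.27. Ly6a of the repair list differed by 1.11, Top2a by 0.79, the claudin Cldn8 by 0.70, the class I genes H2-D1 by 0.40 and B2m by 0.20, the chaperone Hsp90b1 by 0.26 and the ion pump Atp12a by 0.24. Negative differences were found for Fabp2 at -2.58, the tuft marker Dclk1 at -1.96, Cdx2 at -0.79, Prom1 at -0.63, Ang4 at -0.62, Chgb at -0.56, Clca1 at -0.54 and mt-Nd5 at -0.45.

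NF-κB targets were higher in DSS-treated KO for 21 of 30. A lower share of epithelium, raising the markers of all other cells alike, is argued against by the summed CPM of 19 T, NK, B and plasma cell markers, with a log2 ratio from -0.42 to -0.22 over the pairs of libraries, while it was 0.46 to 0.62 for fibroblast and 1.08 to 1.16 for macrophage markers. These sums do not exclude a lower share of epithelium in which the other cell types changed unequally. The lower mitochondrial share as the source is argued against by its size, since its fall could raise all other genes by at most 0.0399 on the log2 scale while the list had a median of 1.12. For a contribution of leukocytes to the rise, the pan-leukocyte list had a median of 0.98 with 13 of 18 members higher, just short of the bound of 1 set before the test. Neutrophil markers were higher for 11 of 12, with a median of 3.41, so leukocyte transcripts rose in the same libraries. How much of the NF-κB rise came from leukocytes and how much from the epithelium itself cannot be told apart. The difference in genotype stays open as well, untested by any sorting of cells.

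Antigen presentation and interferon genes were higher in untreated KO for 13 of 16 and 10 of 23. Leukocytes as carriers of these transcripts are argued against by 0 of 18 pan-leukocyte genes being higher, with 12 of them lower and 6 higher in mean CPM and a sum of 73.9 CPM in WT and 70.4 CPM in KO. Much of the WT sum came from Ptpn6 (25.7 CPM), Cytip (8.11) and Vav1 (7.25), which did not rise under DSS in WT either, so the sum weighs little. Other members had few counts, such as Cd53 with 12 in WT and 9 in KO, so a small rise could be missed. For members without a close paralog, reads shared between paralogs are argued against, since 55% (11 of 20) were higher, compared with 9.19% of all genes tested. These members were picked after the calls were seen, and some, such as Cd74 and Tap1, had already been called higher. Genes with a close paralog, such as Tgtp1, are not covered. A response of the epithelium to loss of Rora is a candidate explanation. A difference in housing, parents or gut microbes between the genotypes was not testable, since nothing in the labels separates these from genotype.

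Proliferation genes were higher in KO for 22 of 23 without DSS and 23 of 23 with DSS. Scaling as the source is argued against by at least 22 members staying higher under library totals and under DESeq2 size factors. More recovery of the lower crypt from DSS-treated KO colons, with its stem markers unchanged, is argued against by 6 stem and crypt genes being lower and 2 higher, with the highest member at 0.53 while the proliferation list had a median of 1.28. This test assumes equal marker levels per crypt cell in both genotypes. More crypt with lowered stem markers is therefore not excluded. In untreated mice 4 stem and crypt genes were lower and 2 higher, but only 1 was lower without untreated KO replicate 1, so there a change in crypt recovery cannot be told apart from a change in division. A higher share of dividing cells in KO may remain as a hypothesis, found and tested on the same data.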

How the results depend on the processing

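Leaving out the mitochondrially encoded genes was chosen after seeing the data, and every other setting before. Among the genes named by the rule, no called gene reversed direction in any setting run. Of 257 gene results, calls ended for 0 with DESeq2 size factors or limma-voom, 2 with library totals, 18 of 252 with the DESeq2 Wald test, 3 without a filter, 0 of 240 with the strict filter, 2 of 243 with only the groups compared, 1 with the replicate block, 15 with effective-length offsets, 114 with the fold threshold and 0 of 249 without the mitochondrially encoded genes. Leaving out 1 library ended between 5 and 16. Of 290 counts of list members, 0 moved by more than 1.5 times with DESeq2 size factors, 11 with library totals, 43 with DESeq2, 4 with limma-voom, 13 without a filter, 17 with the strict filter, 14 of 232 with only the groups compared, 4 with the replicate block, 42 with effective-length offsets, 160 with the fold threshold and 5 without the mitochondrially encoded genes. Leaving out 1 library moved between 23 and 41, many of them counts of 1 or 2 genes. In those fits the lone sample of a group is assumed to vary like the other groups. With library totals 62.8% of called genes were higher for DSS in KO in place of 52.3%, and 59.7% in place of 50.9% for DSS in WT. No scaling moved the median of all genes by more than 0.1 on the log2 scale. Deviations of equal replicate numbers correlated by 0.38 between the DSS-treated groups, by -0.37 and -0.38 between untreated WT and these, and by -0.01 to 0.08 between untreated KO and the other groups. The numbers therefore did not pair the samples across all groups, and a block on them gave 2186, 5791, 5449, 6142 and 3085 genes in the order of the comparisons. Such a block cannot absorb a deviation that runs in opposite order in untreated WT and the DSS-treated groups. Its counts therefore do not exclude a hidden factor of that kind. Depth limits statements on Rora, Rorb, Cxcl1 and genes absent before DSS. It also limits those on genes with few counts before DSS, such as Srgn, Lrg1 and Reg3b.

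With the DESeq2 Wald test the number of genes was 1246 for untreated KO against WT, 3801 for KO against WT under DSS, 3409 for DSS in WT and 1684 for the interaction, and the cause was not tested. With effective-length offsets it was 1290 for untreated KO against WT and 1794 for the interaction, and the cause was not tested. With only the groups compared it was 3403 for untreated KO against WT and 4924 for KO against WT under DSS. For DSS against untreated it was 6156 in WT and 5577 in KO. The main fit gave 2310, 5855, 5573 and 6231 in that order. The shifts went in the direction given by the simulation with a larger spread in DSS-treated KO. Whether that spread caused them was not tested. Requiring a log2 fold change of at least 1 as well gave 144, 928, 801, 1325 and 548 by its construction. With 1 library left out the number went below and above that with all libraries, and the cause was not tested. It ranged from 953 to 3174 for untreated KO against WT, from 4093 to 6182 for KO against WT under DSS, from 3659 to 6426 for DSS in WT, from 4603 to 6263 for DSS in KO and from 1891 to 4444 for the interaction. In untreated KO against WT, 3 values that had passed no threshold changed sign, and the cause was not tested. Tnf was 0.15 without untreated WT replicate 1 (range -0.86 to 0.15), Il1b was 0.15 without that library (range -0.66 to 0.15), and Cxcl1 was -0.25 without it and -0.29 without untreated KO replicate 2 (range -0.29 to 0.81).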

Other observations

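The lists and genes of this part, and the tests of direction with separate WT libraries, were chosen after the values were seen, and the test on a shared direction over all libraries was chosen before. Glycolysis and hypoxia genes were higher in DSS-treated KO than in DSS-treated WT for 20 of 24 and lower for 1 (camera adjusted p = 8.62e-25, and 0.0111 with an estimated correlation). The glycolytic enzyme genes Pgk1 (log2 fold-change = 1.06 ± 0.04), Ldha (0.79) and Gapdh (0.74 ± 0.04) were among them, as were Ak4 (1.84 ± 0.09), the lactate exporter Slc16a3 (1.84 ± 0.09) and the hypoxia-responsive Bnip3 (1.27 ± 0.08), and the lower one was Ndrg1 (-0.32). The DSS response of this list was 5 higher and 10 lower in WT (adjusted p = 0.695 with an estimated correlation) and 17 higher and 2 lower in KO (0.0289), with an interaction for 17 positive and 1 negative (0.0247). Without DSS it was 4 higher and 2 lower between genotypes (0.569). Of 16 keratin and squamous genes 8 were measured, and 2 of these were higher in untreated KO. All 8 were higher in DSS-treated KO against WT (0.0124 with an estimated correlation). Some had few counts, such as Dsg3 with 1 in DSS-treated WT and 55 in DSS-treated KO, and Krt6b with 4 and 29. In the same libraries pan-leukocyte markers were higher for 13 of 18 (median 0.98) and neutrophil markers for 11 of 12.

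Xenobiotic metabolism genes were lower in DSS-treated KO than in DSS-treated WT for 21 of 23 (adjusted p = 0.0111 with an estimated correlation). They included Ugt2b5 (log2 fold-change = -3.00), the carboxylesterase Ces1f (-1.35), Cyp2c65 (-1.33), the efflux pump Abcb1a (-0.99) and Aldh1a1 (-0.84). DSS lowered 19 and raised 1 in WT (0.0265) and lowered 21 in KO (0.00604), and the interaction was negative for 12 and positive for 5 (0.0356). Untreated KO had 13 lower and 4 higher (adjusted p = 9.81e-10, and adjusted p = 0.0665 with an estimated correlation). Several members belong to families of similar genes, whose reads RSEM divides among them. Interferon-inducible GTPase genes were higher in KO for 12 of 15 without DSS (0.00057 with an estimated correlation) and 14 of 15 with DSS (0.00644). DSS lowered 7 and raised 0 of them in WT (adjusted p = 0.0054, and adjusted p = 0.108 with an estimated correlation) and lowered 7 and raised 3 in KO (0.144), and the interaction was positive for 2 (0.214).

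One hypothesis was that the DSS response of KO may be that of WT made larger for every gene, so that the interaction would go in the direction of the WT response. Before the share was computed it was set that this needed at least 75% of the genes called for both to share a direction, and that 60% or less would speak against it. Among 1813 genes the share was 28.7%, which is biased downwards because both values use the same WT libraries. With the WT response from 1 replicate of each WT group and the WT part of the interaction from the other, edgeR called 386 and 459 genes for both. Of these 39.4% (152, exact binomial 95% interval 34.5 to 44.4) and 40.7% (187, 36.2 to 45.4) shared a direction. In this fit the lone WT libraries are assumed to vary like the KO groups, and the intervals treat genes as independent. Among genes chosen without a test, by a mean of at least 100 counts and both values at least 1 in size, the share was 55.4% (36 of 65) and 58.6% (34 of 58), with intervals up to 67.7 and 71.4. The shares among called genes argue against a larger response of every gene, while that of single lists such as NF-κB targets is not excluded.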
